A study of Drosophila melanogaster with 2 samples.

How the data were processed

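DREF, the DNA replication-related element binding factor, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole Drosophila melanogaster embryos of 0 to 24 hours. Per the labels, the flies carried a transgenic DREF fused to eGFP, the fusion protein was precipitated with an antibody against GFP, and chromatin was sheared to fragments of 200 to 800 bp. The series holds 2 samples, which the labels give as separate biological replicates of 1 group. There is no second condition, and the sex of the embryos was not collected, per the labels. All comparisons are therefore between replicates, or between peaks and other positions of the genome.

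The deposited files are peak lists in dm6 coordinates. Per the notes that accompany the files, each replicate has a ranked list and a thresholded list made from its own alignments, and the series has a pair of ranked lists, a thresholded list and a conservative thresholded list made from the alignments of both replicates. Ranking and threshold used the irreproducible discovery rate (IDR), a measure of how consistently a peak ranks in a pair of peak sets. The deposited score was read as a scaled IDR, as is usual for such lists, and every peak of the thresholded lists has a score of 830 or more. The deposited signal is the authors' own value of peak strength, which no source used here describes as scaled for sequencing depth. The deposited lists also give the −log10 of a q-value per peak, with a ceiling of 3.78 that the strongest peaks share. The aligner, the peak caller, their versions and any control library are not given in the sources used here. Read depth is unknown, so no count of reads stands behind any value, and intervals cover only the sampling of peaks or genes.

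The conservative list was the main list. Signals were used to describe and rank peaks within a list. For the correlation between replicates, each peak of the ranked list that led to the conservative list took the signal of the overlapping peak with the nearest summit from each replicate's own ranked list. The 8 further columns of the ranked lists were not used. The ranked list that holds every peak of the conservative list was taken as its source.

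Gene models were those of Ensembl release 115 (FlyBase, BDGP6.54), and sequence was that of the Release 6 assembly, which is dm6. The 6 arms X, 2L, 2R, 3L, 3R and 4 were used, with 13945 protein-coding genes. A peak was at a gene start when its summit lay within 250 bp of the start of any transcript. A gene was called bound when a summit lay within 250 bp of any of its starts. Motifs were searched as exact matches to a consensus on both strands within 100 bp either side of the summit, and 14 motifs were tested, among them a scrambled control with the base composition of the DNA replication-related element (DRE, TATCGATA).

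Summit positions were compared with 1000 random placements on the same arm (one-sided permutation test) and replicate overlap with 100 placements. Motif shares were compared with windows centred 1000 bp to either side of the summit, and with starts of protein-coding genes that had no summit within 250 bp, by two-sided Fisher's exact test. The signal of peaks with and without a DRE was compared with 100000 permutations (two-sided). Gene lists, arms and divergent promoters were compared with all other protein-coding genes by two-sided Fisher's exact test with Benjamini-Hochberg adjustment within each family. Neighbouring genes can share a peak and are not independent, so for the gene lists the bound calls were also rotated 10000 times along the gene order. The tests of arms and divergent promoters were not rotated and count neighbouring genes as independent. Shares carry 95% Wilson intervals. The 21 gene lists were written from general knowledge before the data were examined. All their members matched a protein-coding gene of the annotation apart from Tor, which was left out.

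The genes named in the text follow a rule fixed before the data were examined. It takes Dref itself, every published DREF target of the list, the genes at the 15 strongest peaks, the 3 bound members of highest signal and up to 3 of the first unbound members by name of every other list, the 5 strongest peaks over 1000 bp from any start, and the 3 peaks whose replicate signals differed most. Genes named outside this rule are marked as chosen after their values were seen.

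Some of the statistics were tested on simulated data. Of 5000 simulated summits, 60.2% were placed at starts, and 60.2% were recovered. The background share was taken from the summits known to be placed at random. The recovered value therefore checks only that the placed summits were counted. The permutation tests were not simulated. The DRE was found at 100% of the places where it had been written into the sequence. With gene lists set to 60% bound against 25% of other genes, 99% of 200 lists of 40 genes and 63% of 200 lists of 10 genes were called at an unadjusted p of 0.05. Of 200 unchanged lists of 40 genes, 5% were called.

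The alternatives tried were each replicate's own thresholded list, the other thresholded list, the stronger part of the peaks by signal, other windows around starts and motifs, 1 mismatch in the motif, other definitions of overlap, protein-coding starts only, other divergent distances and rotation of the calls. The part of the conservative list with a q of 0.05 or lower was added after the data were seen, as was the division of peaks into weak and strong. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, Biopython 1.88 and matplotlib 3.10.9.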

Results

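DREF binding was measured in 2 biological replicates of whole Drosophila melanogaster embryos collected over the whole of embryogenesis, from flies carrying eGFP-tagged DREF. DREF is a zinc finger protein that recognises the palindrome TATCGATA, the DRE, found at promoters of replication and proliferation genes. The data are lists of peaks on the dm6 genome with the authors' signal and q-value for each peak, and the read depth of the libraries is unknown. The conservative list made from both replicates held 5355 peaks, of which 5292 lay on the 6 chromosome arms analysed. Replicate 1 alone had 3812 thresholded peaks and replicate 2 alone had 3990.

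The strongest DREF peak of the genome lay at Cyclin B (CycB), the mitotic cyclin. This peak, on arm 2R at 22806821 to 22807283, had a signal of 8990 in the conservative list, 3406 in replicate 1 and 5599 in replicate 2, and its summit was 92 bp upstream of the CycB start. The CycB peak held no exact DRE within 100 bp of its summit. The second peak, on 2L at 825705 to 826121, had a signal of 7842 and lay between the divergent starts of CG3862 and dock, an adaptor protein of axon guidance. The third peak, on 3R at 15263301 to 15263694, had a signal of 7337, lay between Set and the translation initiation factor gene eIF2gamma, and held 3 DREs. The other genes at the 15 strongest peaks were CtsF, CG9175, hppy, CG4360, EndoGI, PRL-1, CG11030, CG5510, eIF3f1, CG2924, Diap1, CG10565 and CG9135, with signals from 6258 to 7209. Every one of these 15 summits lay within 98 bp of a start.

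Peaks differed widely in strength. The median signal of the conservative list was 289.5, with quartiles of 93.1 and 1343. A q-value above 0.05 was attached to 1586 peaks, or 29.6% of the list, against 9.78% of the replicate 1 list and 5.21% of the replicate 2 list. These are called weak peaks here, and the other 3769 strong peaks, a division made after the data were seen. Of the strong peaks, 87.7% overlapped a thresholded peak in both replicates, and 2.52% did so in neither. Of the weak peaks, 2.77% overlapped one in both replicates and 82.9% in neither.

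The first comparison asked whether the replicates bound the same places. Of the replicate 1 peaks, 88.4% (95% interval 87.3 to 89.3) overlapped a replicate 2 peak by at least 1 bp, and 84.4% (83.3 to 85.5) of the replicate 2 peaks overlapped a replicate 1 peak. Random placement gave means of 1.64% and 1.55%, with 2.22% the highest of 100 placements in the first direction and 2.10% in the second. The signals of the replicates had a Spearman rho of 0.947 and a Pearson r of 0.98 on the log2 scale across the 5298 conservative peaks found in both ranked lists. Across the 95395 ranked peaks found in both, most of which did not pass the threshold, rho was 0.409 and r was 0.683. The conservative peaks were selected for ranking alike in both replicates, which raises their correlation. Peaks are not independent replicates, so no p-value is given. Among strong peaks rho was 0.979, and among weak peaks, which span a narrow range of signal, it was -0.103. Signals were higher in replicate 2 at strong peaks, by a median factor of 1.58, but not at weak peaks (0.968) or over all ranked peaks (0.974). The files do not say whether the factor at strong peaks reflects depth.

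Peaks found in the thresholded list of only 1 replicate had low signals. The 434 peaks specific to replicate 1 had a median signal percentile of 8.36 within their list, and the 609 specific to replicate 2 one of 10.7. A q-value above 0.05 was attached to 58.1% of the former and 24.1% of the latter. A DRE lay within 100 bp of the summit in 1.38% (0.635 to 2.98) of the replicate 1 peaks and 39 (4.72 to 8.63%) of the replicate 2 peaks, against 30.6% and 30.9% of the shared peaks of each list. Gene starts were present at 37.8% (33.4 to 42.4) and 64.7% (60.8 to 68.4) of the specific peaks, against 89.6% of the shared ones. Fewer peaks were absent even from the ranked list of the other replicate, 67 in replicate 1 and 104 in replicate 2. Of these, 2.99% (0.822 to 10.2) and 20.2% (13.6 to 28.9) had a DRE, and 40.3% and 74.0% lay at a gene start. A q-value above 0.05 was attached to 44.8% and 8.65%. The 3 peaks with the largest differences between replicates lay at TfIIFalpha, Fancm and CG17776, and each shared its interval with a stronger summit. At TfIIFalpha the second summit was matched to one in replicate 1 (43.1) but to the main summit, 210 bp away, in replicate 2 (883), where no second summit was listed. At Fancm and CG17776 it was replicate 1 that listed the main summit alone.

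The next comparison asked where in the genome DREF bound. Gene starts were the main site, as at CycB, Set and eIF3f1. Of the 5292 summits, 69.0% (67.7 to 70.2) lay within 250 bp of a start, against a mean of 7.55% and a highest value of 8.71% in 1000 random placements (one-sided permutation p = 0.001, the smallest these placements can give). The share was 87.4% (86.3 to 88.4) for strong peaks and 24.7% (22.6 to 26.9) for weak peaks. Strong summits lay a median of 40 bp from the nearest start. By annotation, 67.8% of strong summits were intergenic and 15.1% in a 5' UTR, which makes up 3.38% of arm length. Coding sequence held 0.669% of strong summits and 30.3% of weak summits, against 16.7% of arm length.

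Few strong peaks lay far from genes' starts. Over 1000 bp from any start lay 192 strong peaks, or 5.14%, and 858 weak peaks, or 55.2%. The strongest distal peak was on the X at 6741100 to 6741466, with a signal of 4816 and 2 DREs, 1220 bp from the start of a small nucleolar RNA gene. The next were on 3R at 9496732, 1596 bp from RhoL, and on 3L at 18828352, 5906 bp from Cat, the catalase gene. The other 2 of the 5 strongest were on 2R at 24337509, 1703 bp from a long non-coding RNA gene, and on 3L at 16037156, 1686 bp from CG5895. All 5 were intergenic.

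The DRE was strongly enriched at DREF summits. An exact DRE lay within 100 bp of 1058 summits, or 19.99% (18.9 to 21.1), and in 0.529% (0.408 to 0.686) of windows 1000 bp away (odds ratio 47.0). Starts of genes without a peak carried it in 1.05% of cases (odds ratio 23.6). Both p-values of the two-sided Fisher's exact test were below the smallest number that double precision holds. Among strong peaks the share was 28.0% (26.5 to 29.4). Among weak peaks it was 0.836% (0.489 to 1.43), against 0.514% in their flanking windows, a difference that did not pass the test (Fisher's exact p = 0.235). With 1 mismatch allowed, 43.9% of all summits and 7.68% of flanking windows had a match. The scrambled control was found at 5 summits, or 0.0945%, and in 10 flanking windows, also 0.0945%.

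Other motifs were enriched at DREF summits too. The inner palindrome ATCGAT lay near 41.1% of summits, at 5.81 times the flanking share, and CGATA, the site of the boundary factor BEAF-32, near 60.8%, at 2.70 times. Both are parts of the DRE. Motif 1, the site of M1BP, was found at 4.37% of summits, 25.7 times the flanking share and 1.97 times that of starts without a peak (Fisher's exact test with Benjamini-Hochberg adjustment over 14 motifs, adjusted p = 4.8e-88 and 1.6e-14). Core promoter motif 7 was at 25.6% of summits and 8.53% of starts without a peak, and the core promoter E-box at 10.3%, 2.01 times its share there. The TATA box, at 2.55%, and the initiator, at 0.964%, were rarer than at starts without a peak, by factors of 0.316 and 0.245 (Fisher's exact test, adjusted p = 5.1e-51 and 1.3e-31). GAGA, the site of GAGA factor, was rarer too, at 0.465 times. Zelda sites, with a ratio of 0.788, did not pass this test (Fisher's exact, adjusted p = 0.173). Every window of this background lay at a start, while 69.0% of summits did, so position may lower these ratios. Against flanking windows the TATA box, the initiator and GAGA had ratios of 1.09, 1.26 and 0.951. None passed that test (adjusted exact p = 0.478, 0.249 and 0.687). Among strong peaks the TATA box stayed rarer than at starts without a peak (3.13% against 7.96%), but not than in flanking windows (2.15%).

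Peaks with a DRE were the stronger ones by median, but only 45.7% of the strongest decile by signal had one. Peaks with a DRE had a median signal of 1584 and those without one 169.7, a log2 difference of 3.22 (two-sided permutation p = 1e-05, the smallest that 100000 permutations can give). In replicate 1 the medians at the same peaks were 614 and 75.8, and in replicate 2 they were 980 and 98.1. Among strong peaks alone the log2 difference was 1.63, so part of the contrast came from weak peaks, few of which have a DRE. In the list of replicate 1 alone it was 1.66, in that of replicate 2 alone 1.87, and in the stronger part of the conservative list by signal 0.54. The median rose with the number of DREs, from 1524 with 1 DRE to 1862 with 2 DREs in 91 peaks, and 2813 with 3 or more in 7 peaks. Across peaks, signal and DRE number had a Spearman rho of 0.446. It was 0.362 among strong peaks and 0.195 in the stronger part of the list by signal. DREs lay close to the summit. Of 1332 peaks with a DRE within 500 bp, 75.3% had the nearest one within 50 bp, against 11.5% for uniform positions (one-sided permutation p = 0.001, the smallest that 1000 draws can give), and its median distance was 23.5 bp.

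**Figure D1:**
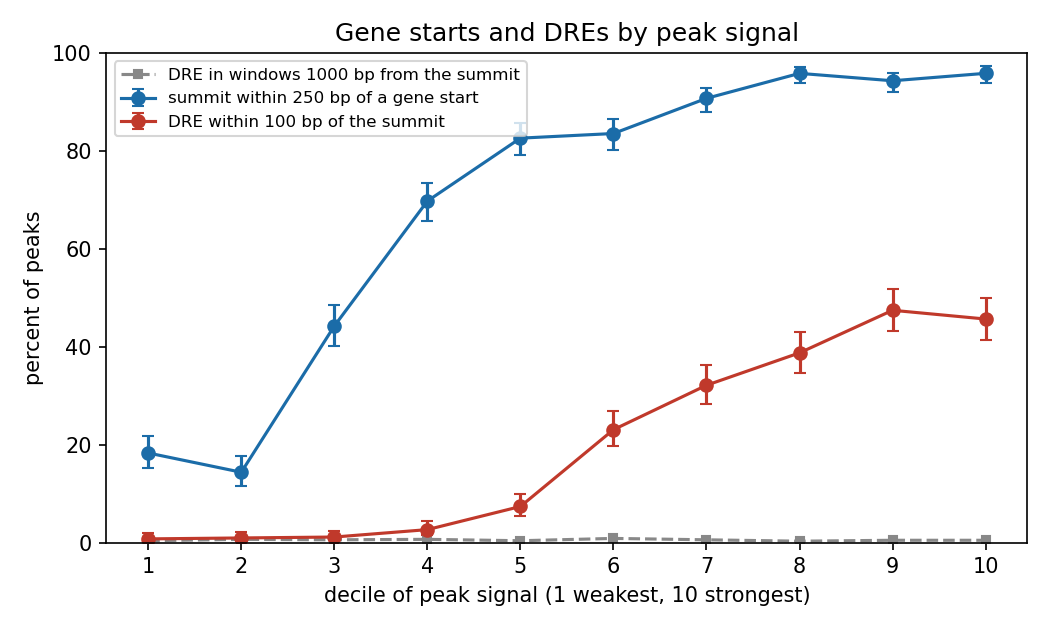
Percent of conservative peaks at a gene start and with a DRE (y axis), by decile of peak signal from weakest to strongest (x axis), with 95% Wilson intervals; the dashed line is the DRE share of windows 1000 bp from the summits. Gene starts go from 18.3% in the weakest decile to 95.8% in the strongest, and DREs from 0.755% to 45.7%.

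**Figure D2:**
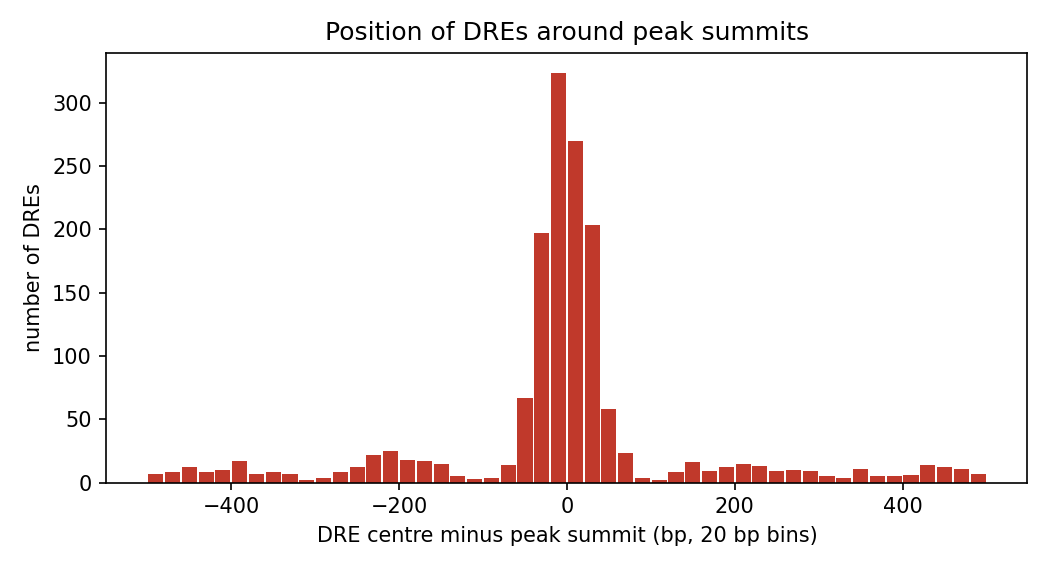
Number of DREs (y axis) by distance from the peak summit in 20 bp bins (x axis) for peaks on the 6 arms. DREs pile up at the summit and thin out within 100 bp of it.

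DREF bound the starts of 4272 protein-coding genes, 30.6% (29.9 to 31.4) of the 13945 on the arms. For 369 of them the call rested on a weak peak, and 3903 genes were bound by strong peaks alone. Dref itself was bound, with a summit 8 bp inside the gene on 2L at 9967221, a signal of 1674 and no exact DRE. Of 21 published DREF targets 18 were bound (85.7%, 65.36 to 95.02, adjusted exact p = 9.2e-07 over 21 lists), with a median signal of 2228, and 10 of the 18 peaks held a DRE. With summits within 100 bp of a start 14 were bound (66.7%, adjusted exact p = 0.000264), and E2f1, PolG2, brm and bsk lost their call. PolA2 (4250) and PolA1 (3599), which encode subunits of DNA polymerase alpha, together with CycA (3426), hpo (2706), PCNA (2666), SkpA (2488) and Orc5 (2369) had the highest signals. They were followed by p53 (2236), Myb (2234), Tbp (2221), Raf (1921), PolG2 (1598), mtSSB (1457), TFAM (1303) and bsk (1051). Weaker peaks lay at brm (326) and E2f1 (178). PCNA, the sliding clamp of DNA replication, had its summit on 2R at 20262904, 21 bp upstream of the start, with 1 DRE and signals of 1021 in replicate 1 and 1653 in replicate 2. The remaining targets, Trf2, mor and osa, were not bound in the conservative list. The ranked list held peaks at the starts of mor (750) and osa (4234) that passed the score of the thresholded list and were left out of it, and no source used here gives the reason.

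Genes of replication and the cell cycle were bound more often than other genes. Of 43 replication genes 29 were bound (67.4%, 52.5 to 79.5), against 30.5% of other genes (odds ratio 4.72, two-sided Fisher's exact test with Benjamini-Hochberg adjustment over 21 lists, adjusted p = 2.6e-06). After the polymerase alpha genes, RfC3 of the clamp loader had the highest signal, 3309, while Cdc45, Fen1 and Mcm10 were not bound. Of 28 cell cycle genes 16 were bound (57.1%, 39.1 to 73.5, adjusted exact p = 0.00453). CycB was joined by Cdk2 (4086) and grp, the Chk1 checkpoint kinase (3825), and Cdk1, CycD and Myt1 were not bound. DNA repair genes were bound in 15 of 26 cases (57.7%, adjusted exact p = 0.00548; 42.3% and 0.0722 with summits within 100 bp of a start), led by Ku80 (2460), FANCI (1811) and mus304 (1711), with Blm and Msh6 among the unbound. In the smaller telomere capping list, 6 of 9 were bound (66.7%, 35.4 to 87.9, adjusted exact p = 0.028). These were led by moi (1722), mre11 (1513) and rad50 (1348), and HipHop, nbs and tea were not bound. The telomere call was lost without the weak peaks, at 55.6% bound (adjusted exact p = 0.128).

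Translation and mitochondrial genes were bound in large numbers. Of 93 cytosolic ribosomal protein genes 67 were bound (72.0%, 62.2 to 80.1, odds ratio 5.91, adjusted exact p = 2.0e-15). RpS30 (6130), RpL41 (4826) and RpS28a (4339) had the highest signals, and RpL10, RpL10Aa and RpL13A were among the unbound. Of 73 mitochondrial ribosomal protein genes 51 were bound (69.9%, 58.6 to 79.2, adjusted exact p = 3.3e-11), led by mRpL4 (3723), mRpL48 (3398) and mRpL3 (2986). The unbound included mRpL11, mRpL15 and mRpL21. Aminoacyl-tRNA synthetase genes were bound in 21 of 33 cases (63.6%, adjusted exact p = 0.000185; 36.4% and 0.0538 in the stronger part of the peaks by signal), among them TrpRS (4029), LeuRS-m (2483) and AspRS (2355) but not AsnRS-m, CysRS-m or GluRS-m. The mitochondrial genome list had 8 of 10 bound (80.0%, 49.0 to 94.3, adjusted exact p = 0.00277), with mTTF (3741) ahead of PolG2 and mtSSB, and PolG1 and mtTFB1 unbound. Of 92 oxidative phosphorylation genes 49 were bound (53.3%, 43.1 to 63.1, adjusted exact p = 1.7e-05). UQCR-14 (5424), ATPsynF (4584) and ND-B14.5A (3718) led, and ATPsynB, ATPsynC and ATPsynCF6 were unbound.

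Chromatin, transcription and growth genes followed the same direction. Of the 11 listed genes of DREF and its partners 10 were bound (90.9%, 62.3 to 98.4, adjusted exact p = 0.000121). E(bx) (3803) and Iswi (3192), subunits of the nucleosome remodeller NURF, and Caf1-55 (2753) led, and only Trf2 was unbound. Of 15 insulator and architectural protein genes 11 were bound (73.3%, 48.0 to 89.1, adjusted exact p = 0.00132), among them Cp190 (3104), Ibf2 (1930) and ZIPIC (1649), and Clamp, M1BP and Trl were not. TFIID and Mediator genes were bound in 28 of 45 cases (62.2%, adjusted exact p = 3.1e-05), with Taf10 and Taf10b sharing 1 peak (3761) and MED9 next (3589), and CycC, MED1 and MED11 unbound. In the Hippo and TOR growth pathways 16 of 25 were bound (64.0%, 44.5 to 79.8, adjusted exact p = 0.0012). The apoptosis inhibitor Diap1 (6387), the Hippo pathway kinase gene wts (5333), which held 3 DREs, and chico (4312) led, with InR, Thor and ds unbound. Proteasome genes were bound in 25 of 48 cases (52.1%, 38.3 to 65.5, adjusted exact p = 0.0034). Rpn6 (5366), Rpt5 (3367) and Rpt6 (3311) led, and Prosalpha1, Prosalpha1R and Prosalpha2 were unbound.

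Genes of tissue identity and specialised function were bound less often. Here and for the lists above, the comparison was with all other protein-coding genes. These were not matched for expression or open chromatin in the embryo, which were not measured here. The contrast between lists therefore does not tell a choice of targets by DREF from a difference in promoter activity. Only 3 of 32 segmentation and Hox genes had a peak (9.38%, 3.24 to 24.2, adjusted exact p = 0.00703), and their signals were low, at 126 for bcd, 79.8 for hry and 57.0 for wg, the last 2 weak peaks. Abd-B, Antp and Dfd had none. Of 23 muscle structure genes only Tm1 (1408) was bound (4.35%, adjusted exact p = 0.00558), and Act57B, Act79B and Act87E were not. Of 24 neuronal genes only elav (183) was bound (4.17%, adjusted exact p = 0.00396), and Appl, ChAT and DAT were not. With summits up to 1000 bp from a start, 17.4% of the muscle genes and 20.8% of the neuronal genes were bound, Act57B and Appl among them, and neither list passed the test (adjusted exact p = 0.0556 and 0.137). Odorant and gustatory receptor genes had 3 of 119 bound (2.52%, 0.861 to 7.15, adjusted exact p = 1.8e-14). They came from 2 weak peaks, in the coding sequence of Or43a (63.5) and of Gr59e (82.3), the latter also within 250 bp of the start of Gr59f, and Gr10a, Gr10b and Gr21a had none. Cuticle protein genes had 2 of 118 bound (1.69%, 0.466 to 5.97, adjusted exact p = 2.0e-15), TwdlK (112) and Cpr30F (69.6), and Ccp84Aa, Ccp84Ab and Ccp84Ac had none. In the list of replicate 2 alone, 0 of the segmentation, receptor and cuticle genes were bound; in that of replicate 1 alone, 2 segmentation genes, 1 cuticle gene, 0 neuronal genes and 0 receptor genes were. All these lists stayed below other genes in both. None of the 111 replication-dependent histone genes was bound, His1:CG31617, His1:CG33801 and His1:CG33804 included. Their repeated cluster on 2L, from 21416953 to 21541681, held 6 ranked peaks, where the density of the arm would give 112, so binding there was not detectable in these lists. The other lists all kept an adjusted p under 0.05 when the calls were rotated along the gene order, with 0.03 the highest permutation value, for telomere capping.

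**Figure D3:**
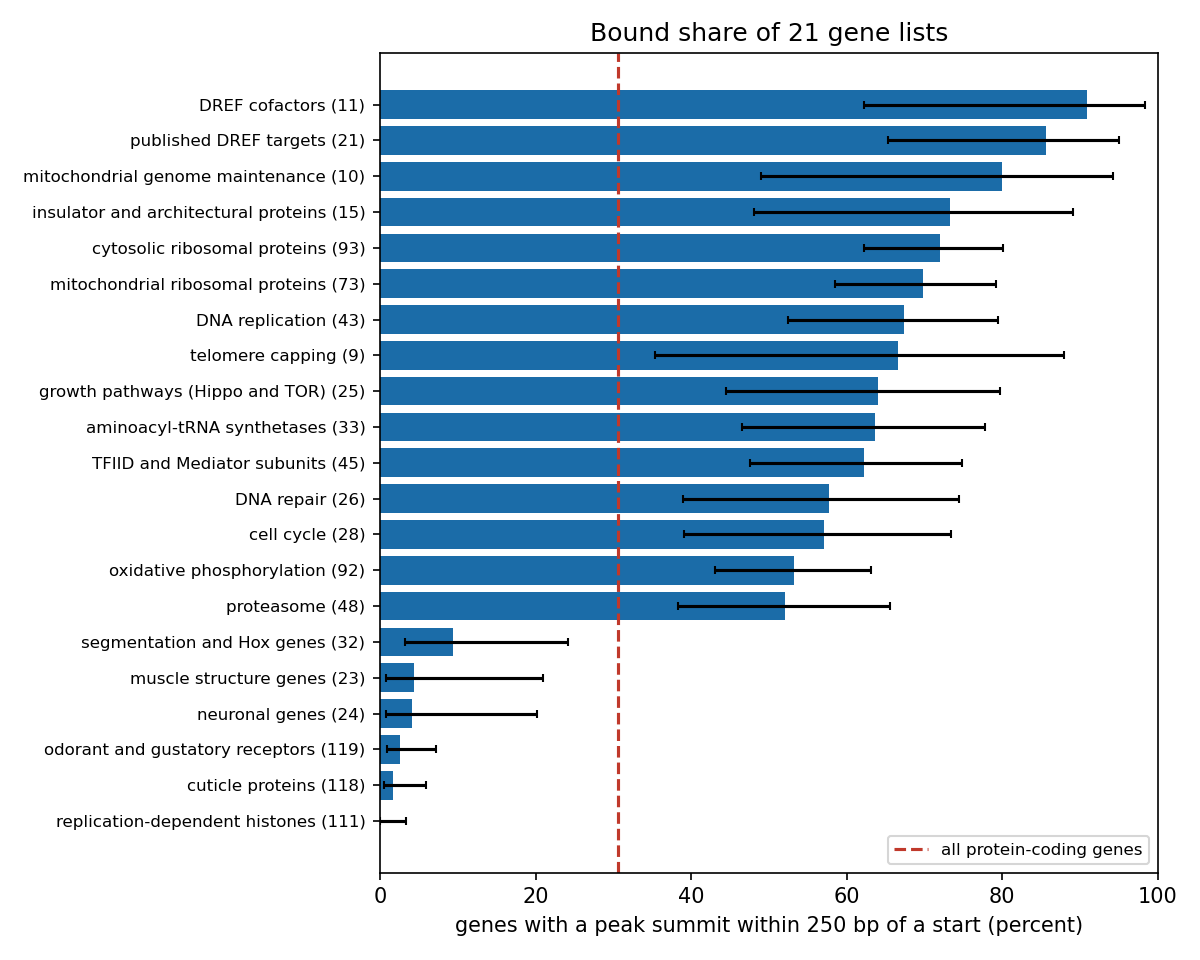
Percent of genes with a DREF summit within 250 bp of a start (x axis) for 21 gene lists (y axis, number of genes in parentheses), with 95% Wilson intervals; the dashed line is the share of all protein-coding genes. The 15 upper lists lie above that line and the 6 lower ones below it.

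Divergent gene pairs were a favoured place of binding, as at CG3862 and dock, Set and eIF2gamma, and EndoGI and PRL-1. Of 3481 protein-coding genes with a divergent start within 500 bp 57.6% (55.9 to 59.2) were bound, against 21.7% (20.9 to 22.5) of other genes (odds ratio 4.90, with a Fisher's exact p below the smallest number that double precision holds). Of 1690 mutual pairs, both genes were bound in 814, or 48.2%, and 1 of them in 314, or 18.6%. A divergent pair has more starts near any summit than a single gene, which raises its chance of a call. The test also counts the genes of a pair as independent, though the same summit can call both. When summits had to lie within 100 bp of a start, the shares were 46.1% and 18.7%.

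Genes of the X chromosome were bound more often than those of other arms. Of 2196 X-linked genes, Myb, Raf and SkpA among them, 882 were bound (40.2%, 38.1 to 42.2), against 28.9% of genes elsewhere (odds ratio 1.66, two-sided Fisher's exact test, adjusted p over 6 arms 2.5e-24). Arms 3L (26.9%, adjusted exact p = 5.0e-06) and 2L (28.0%, adjusted exact p = 0.00158) were below the other arms. Chromosome 4 had 11 of 80 genes bound (13.8%, 7.85 to 23.0, adjusted exact p = 0.00119), and in the list of replicate 2 alone this was 21.2% and did not pass the test (adjusted exact p = 0.207). Arms 2R, at 31.2%, and 3R, at 29.5%, did not pass the test. Of the ranked peaks that passed the score and were left out of the list, more lay on 3R (79) than on any other arm, which can lower its share. All these arm tests count neighbouring genes as independent, though genes can share a peak. Weak peaks showed another distribution, with 8.23% (6.97 to 9.70) of them on the X, against 22.7% (21.4 to 24.1) of strong peaks.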

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

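Some tests below were chosen only after the result was seen: the division into weak and strong peaks, the criterion for weak peaks at starts, the share of weak peaks in the lists of 1 replicate, and the look at starts among peaks below the threshold, which took the place of a DRE test that did not pass.

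A signal was present in peaks that the comparisons did not use. The ranked list held 235 peaks that passed the score of the conservative list and were left out of it. Of the 153 on the 6 arms, 54.9% lay at a gene start (highest of 1000 random placements 16.3%) and 10.5% had a DRE, against 0.327% of flanking windows (Fisher's exact p = 1.6e-07). By arm, 79 were on 3R, 32 on 2L, 17 on the X, 12 on 3L, 11 on 2R and 2 on chromosome 4. The strongest lay on 3R at 15131793, with a signal of 6506, at the start of CG42788, a gene chosen after its value was seen. Including them would add 82 bound genes, among them kibra (3285), mRpL47 (5941), ATPsynC (519) and Syx1A (175), as well as mor and osa (chosen after their values were seen). A further 58 lay on unplaced scaffolds, where the conservative list has no peak.

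The conservative list held 63 peaks outside the 6 arms, 59 on unlocalised scaffolds of the X with a median signal of 109 and 4 on the Y. Of the 5000 strongest ranked peaks below the threshold, 13.6% lay at a gene start, against 8.94% in the highest of 1000 random placements, while 0.66% had a DRE and 0.48% of their flanking windows did (Fisher's exact p = 0.158).

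The 1586 weak peaks make up 29.6% of the conservative list. Weaker binding at promoters met its first criterion, since 24.7% lay at a start against 9.65% in the highest random placement; the later criterion, over 50% at a start, was not met, so it may explain a part but not most of them. They were less common in both lists of a single replicate, at most 9.78%; a threshold that admits weaker peaks when 2 replicates are compared was proposed from these shares, which therefore do not test it, and stays open. Background regions that passed the threshold stay open. The DRE share was 1.62 times that of flanking windows, with a test that did not pass (Fisher's exact p = 0.235). ATCGAT and CGATA did not exceed the flanks, at 0.874 and 0.969 times. Motif 1, motif 7 and the E-box were among the motifs that did, at 15.3, 1.70 and 2.25 times (adjusted exact p = 1.1e-07, 1.0e-06 and 9.9e-06). Motif 1 was at 23 weak peaks and in 3 flanking windows. Against starts without a weak peak, which include those with a strong one, these ratios were 0.472, 0.814 and 0.647 (adjusted exact p = 0.000201, 0.00754 and 0.000201). Since 24.7% of weak summits lay at a start, position may affect both comparisons.

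Of 3737 strong peaks on the arms, 2692 had no exact DRE within 100 bp, Dref and CycB among them. A DRE with 1 mismatch does not account for most: such sites exceeded those of flanking windows by 36.1 percentage points, to 43.7% of these peaks. A DRE beyond that window, up to 250 bp, exceeded the flanks by 2.99 points. Motif 1 was present in 5.98%, against 4.50% of strong peaks with a DRE (Fisher's exact p = 0.0804). This leaves its part open, though at that share it can account for few of these peaks. Core promoter motif 6 (2.27% against 1.82%), motif 7 (31.3% against 32.5%) and the E-box (12.4% against 13.2%) did not pass this test (adjusted exact p = 0.711, 0.711 and 0.718). None of these 3 was thus shown to be more common where the DRE was missing. Parts of the DRE were enriched, ATCGAT at 38.9% against 7.63% of flanking windows and CGATA at 68.9% against 23.2%, so looser matches stay open for some of these peaks, and recruitment by other proteins was not tested.

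Weak peaks of the conservative list were rare on the X, which held 8.23% (6.97 to 9.70) of them and 17.6% of arm length; among those of the replicate lists it held 10.7% (7.89 to 14.2) in replicate 1 and 14.5% (10.29 to 20.05) in replicate 2. The X share of protein-coding genes, 15.7%, lies above the first 2 intervals but within that of replicate 2, where the pattern is not shown. Peaks below the threshold were as rare there, 8.30% of the 5000 strongest. A lower background on a chromosome present once in males could lower the X share, but whether by this much was not calculated. The peaks below the threshold may share any other cause of the weak ones, so they do not decide it. The sex of the embryos was not collected, and no biological explanation was tested.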

How the results depend on the processing

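The part with a q of 0.05 or lower was chosen only after the data were seen, and the other settings before the data were examined. A score of 830 or more was to be a stricter threshold, but every peak already passes it, so it gave no value. No paired analysis was possible because there is only 1 group. Read depth is unknown, so what depth limits could not be measured. The promoter share, the DRE share, the DRE signal difference, the DRE distance, the divergent pairs and the X kept their direction and their side of the threshold under every setting run; the promoter share ranged from 61.5% to 92.0% the DRE share from 18.7% to 43.9% and the log2 signal difference from 0.54 to 3.66. Numbers of peaks went from 3812 to 3990 without either replicate, and bound genes from 3750 to 4006. Over all settings, bound genes went from 3012 with the stronger part of the peaks by signal to 5190 with a start window of 1000 bp.

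Keeping the stronger part of the peaks by signal left 2677 peaks by construction. Replicate overlap then rose to 99.0% of replicate 1 and 94.9% of replicate 2 peaks, and at a q of 0.05 or lower it was 94.1% and 85.9%. Asking for 50% of both intervals gave 80.5% and 77.3%, and summits within 100 bp gave 86.5% and 82.7%. Peaks specific to a replicate became 19.4% and 22.5% with the 50% rule, and 1.77% and 2.63% when the ranked list of the other replicate was searched, which follows from the definitions. The signal correlation moved from 0.409 to 0.947 among thresholded peaks and to 0.683 as Pearson r.

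Of 180 list results under other settings, the histone genes left out, 174 kept their call and 6 lost it, none reversed. Telomere capping fell under the threshold at 55.6% bound with a q of 0.05 or lower and at 44.4% with a start window of 100 bp, and DNA repair at 42.3% with that window. Aminoacyl-tRNA synthetases did so at 36.4% with the stronger peaks. Muscle structure genes (17.4%) and neuronal genes (20.8%) lost their call with a window of 1000 bp. Arm 3R passed the test at 23.9% with a window of 100 bp, and chromosome 4 lost its call at 12.5% with the stronger peaks and at 21.2% without replicate 1, against 13.8% without replicate 2. Arm 2R, never past the test, reversed its direction without replicate 2 (26.3%, against 29.1% without replicate 1). Beyond the definitions, the cause was not tested. Of 1128 calls of named genes, 1057 were the same, 48 were lost and 23 gained. With a start window of 100 bp, 15 named genes lost their call, among them E2f1, PolG2, brm, bsk, E(bx), RpS28a, LeuRS-m and mus304. The peaks at wg, Or43a and Cpr30F were lost in all 5 other peak sets: either replicate alone, the other thresholded list, the stronger part by signal and a q of 0.05 or lower.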

Other observations

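The gene families below were chosen only after the data were seen, from all 94 symbol stems with at least 8 protein-coding genes. All 8 CCT genes, which encode the subunits of the cytosolic chaperonin, were bound (Fisher's exact test with adjustment over 94 stems, adjusted p = 0.000427), with signals from 187 at CCT6 to 3855 at CCT2. Of 15 Usp deubiquitinase genes 14 were bound (adjusted exact p = 5.3e-06), led by Usp1 (5725). Of 21 Nup nuclear pore genes 17 were bound (adjusted exact p = 2.0e-05), led by Nup50 (4636), and of 20 Atg autophagy genes 14 (adjusted exact p = 0.00148), led by Atg8a (3577). Among 44 eIF translation initiation genes 27 were bound (adjusted exact p = 0.000175).

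Other families were nearly free of peaks. None of the 51 Obp odorant binding protein genes (adjusted exact p = 1.7e-07) or the 28 Sfp seminal fluid protein genes (adjusted exact p = 0.000285) was bound. Only 1 of 60 Ir ionotropic receptor genes (adjusted exact p = 1.8e-07) and 3 of 85 Cyp cytochrome P450 genes (adjusted exact p = 6.7e-09) had a peak. Genes that do not encode proteins were bound seldom, with 138 of 3261 long or other non-coding RNA genes (4.23%, 3.59 to 4.98) and 4 of 290 tRNA genes (1.38%, 0.538 to 3.49). Of the 2331 non-coding RNA genes with a start over 1000 bp from any coding start, 1.33% were bound.

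The lists of oxidative phosphorylation and proteasome genes hold copies of other members, named by a suffix L, R or T. The test of these copies was chosen before their binding was looked at. Of 34 copies 2 were bound, Prosbeta2R2 and Rpt3R (5.88%, 1.63 to 19.1), against 21 of their 28 parental genes (56.6 to 87.3%, two-sided Fisher's exact p = 1.6e-08). The test took all these genes as unpaired and independent, though several copies share a parental gene. Pairs with only the parental gene bound include COX4 and COX4L, ND-24 and ND-24L, and Rpt4 and Rpt4R. The genes of this paragraph were named after their values were seen. The hypothesis that DREF binding may follow the parental gene and not its copy rests on the counts of this paragraph alone. Loss of reads that match both copies could lower the parental genes too, most of which were bound. A gene can lose reads and still be called bound, however, and how uniquely reads map at these starts was not measured. The count of bound parental genes therefore does not exclude such a loss. How these copies are expressed was not measured here.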
